A study of Homo sapiens with 8 samples.

How the data were processed

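RNA of 8 samples of the hepatic stellate cell line LX-2 was sequenced, 4 treated for 72 h with recombinant TGF-β1 and DMSO and 4 with TGF-β1 and 5 µM ML290. Cells were lysed in Trizol and RNA was purified on columns, per the labels' protocols. STAR, Partek and GRCh38 are named per the submitters' processing notes, with no versions or roles. The annotation, the counting, the use of strand, the filter, the normalization and the statistical model are not given in the sources used here.

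The data used were 1 table of the authors' own comparison, with 14870 rows and 14869 distinct gene symbols. The group means that the authors deposited are least-squares means per the file headers, and are a signal on the scale of normalised read counts, with a scaling that is not given. They sum to 698420 for ML290 and 702849 for DMSO. Whether they were divided by gene length is not given. Most low values of different genes lie on multiples of a common step, as given below, which argues against such a division. The column of totals that the authors deposited is also a signal, equal to 4 times the sum of both group means in each row. The ratio and the signed fold that the authors deposited are the quotient of the group means, ML290 over DMSO, and its inverse with a minus sign where it is below 1. The p-value and its step-up adjusted p-value were made by the authors with a test that is not given. The adjusted p equals Benjamini-Hochberg adjustment over 14872 tests, 2 more than the rows used, both ranked first. Those 2 are not analysed here.

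Depth was read from the low values. The summed values of the 4 libraries of a group mostly lie near whole multiples of 0.0522 for ML290 and 0.0476 for DMSO, after a fitted offset. Within 0.15 of a whole read lay 87.9% of 595 low ML290 values and 95.7% of 555 low DMSO values. A step fixed beforehand would give 30% by chance. These steps and the offset were fitted to the same values, so 30% is not their exact chance share. If values are scaled to 1000000 reads, the steps correspond to about 19200000 and 21000000 reads per library. The smallest total is about 18.0 reads over 8 libraries. Reads per library could not be recovered, because the table holds group means.

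From the table were computed the log2 of the ratio, the level (the total divided by 8), the counts of genes past an adjusted p of 0.05 in each direction, and tests of gene lists. Because the file holds comparison statistics and no values per sample, the design written before the data were examined sent all results to the authors' adjusted p and to random lists. For each of 37 lists fixed before the data were examined, the percentile of the median log2 ratio among 10000 random lists of the same size, matched in 20 bins of level, gave a two-sided permutation p, adjusted by Benjamini-Hochberg over the 33 lists with at least 5 listed members. What is called a permutation here draws genes at random and relabels no samples, so its p does not reflect the spread between replicates. Fisher's exact test of called members among all rows was run beside it and passed 19 lists. Older gene symbols were matched, and 13999 rows (94.1%) matched GENCODE 29 on GRCh38, which gave the coordinates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

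The list test was tested on simulated lists of 20 genes drawn from the 14870 rows. The log2 ratios were first shuffled among rows of like level, and fewer random lists were drawn than in the main test. It called 0 of 80 unshifted lists, 5 of 20 with a log2 shift of 0.2 and 17 of 20 with a shift of 0.4. Genes of a simulated list were thus independent of each other. The simulation therefore does not show how often real lists, whose genes move together, pass without an effect. The read step of a simulated group of 4 libraries was recovered with an error of 0.00446%. This is a lone draw, with an error smaller than the spacing of the steps searched, so it does not measure accuracy.

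Named genes were chosen by a rule set before the data were examined. They are the 8 largest increases and the 8 largest decreases among genes past the threshold with a mean level of at least 10 and an official symbol, then 18 genes fixed for their role, and in each list the 2 to 4 members with the smallest adjusted p. A few further members were named after their values were seen, because they are the exceptions of a list or common reference genes: COL27A1, COL13A1, SMTN, CNN1, CCL2, CCL7, VCAM1, TFEB, ATF4, TNFAIP3, TGFBI, SMAD7, FGF5, ACTB, ACTG1 and RPLP0, and the genes named by symbol family in the closing section. Some genes that the rule takes are not reported here.

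Alternatives tried were another adjustment, a filter on level, stricter thresholds, random lists without matching and the list mean, and, after the data were seen, an unadjusted threshold, centring, removal of ambiguous rows and subtraction of a trend in transcript length and GC content. Genes were also grouped by the start of their symbols after the data were seen.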

Results

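The study measured messenger RNA in LX-2 cells, an established human hepatic stellate cell line, after 72 h with recombinant TGF-β1, the cytokine that drives stellate cells to a matrix-producing, contractile state. One group of 4 samples also received the solvent DMSO, and the other group of 4 received 5 µM ML290, a small-molecule agonist of the relaxin receptor RXFP1. The comparison asks what ML290 changed in stellate cells treated with TGF-β1. There was no group without TGF-β1 and none without the receptor. Values were 1 normalised read count per gene and group, the authors' group mean over 4 samples, with the authors' own test. No value per sample was used here, so no SD, SE or count of samples showing a direction stands beside the values below. Only the adjusted p of the authors' deposited table does, from a test that is not given. It is not itself a measure of the spread between replicates. The low values of the table lie on steps of 1 read that correspond to about 19200000 reads per ML290 library and 21000000 reads per DMSO library, if the values are scaled to 1000000 reads. Depth per sample is otherwise unknown.

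With ML290, transcripts of the matrix, the contractile apparatus, mitosis and cholesterol synthesis were lower, and transcripts of inflammatory cytokines, amino acid supply, the unfolded protein response and lysosomes were higher. The authors' deposited table puts the collagen chain COL3A1 3.88-fold lower and the smooth muscle actin ACTA2 2.98-fold lower with ML290. It puts the neutrophil chemokine CXCL8 87.4-fold higher and the cystine transporter SLC7A11 4.89-fold higher in the authors' deposited table. At an adjusted p under 0.05 in the authors' deposited table, 5226 of 14870 rows, 1 per gene except for BRD2 with 2, differed (35.1%), 2901 higher and 2325 lower with ML290. The median change was 1.35-fold among the higher and 1.33-fold among the lower genes in the authors' deposited table. A fold of at least 2 either way left 598 genes of the authors' deposited table, 319 higher and 279 lower, and a fold of at least 1.5 left 1604. Of the 598, only 189 had a mean level of at least 10, 125 higher and 64 lower. An adjusted p under 0.01 left 3413.

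Among genes with a mean level of at least 10, the 8 with the largest increases in the authors' deposited table were CXCL8, IL6, SERPINB2, MMP1, IL1B, HDAC9, RPLP0P2 and SLC7A11. The cytokine IL6 had a mean of 20.99 with ML290 against 2.27 with DMSO in the authors' deposited table, 9.24-fold higher (adjusted p = 1.70e-08). CXCL8 went from 1.45 to 126.5 (adjusted p = 3.71e-10), and the interleukin IL1B was 7.32-fold higher (adjusted p = 3.86e-07), both in the authors' deposited table. The plasminogen activator inhibitor SERPINB2 was 8.33-fold higher and the histone deacetylase HDAC9 5.31-fold higher in the authors' deposited table. RPLP0P2 was 5.00-fold higher in the authors' deposited table, but it is a pseudogene of RPLP0, itself 1.13-fold higher at a mean of 473.4, and the reads of the pair are hard to tell apart. On GRCh38 with GENCODE 29, CXCL8 lies on chromosome 4 from 73740506 to 73743716, IL6 on chromosome 7 from 22725884 to 22732002, IL1B on chromosome 2 from 112829751 to 112836903 and SLC7A11 on chromosome 4 from 138164097 to 138242349, all of them protein-coding genes.

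The 8 largest decreases at that level in the authors' deposited table included TENM2, MEST, CXCL12, COL3A1, SCG2 and ACTG2. The teneurin TENM2 was 5.76-fold lower and the imprinted gene MEST 5.11-fold lower (adjusted p = 3.43e-08 and 5.27e-10) in the authors' deposited table. The chemokine CXCL12 fell from 342.2 to 86.3, 3.96-fold lower (adjusted p = 2.27e-07) in the authors' deposited table. The granin SCG2 was 3.19-fold lower and the enteric actin ACTG2 3.14-fold lower in the authors' deposited table. TENM2 lies on chromosome 5 from 167284799 to 168264157, MEST on chromosome 7 from 130486171 to 130506465 and CXCL12 on chromosome 10 from 44370165 to 44386493 of GRCh38.

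**Figure D1:**
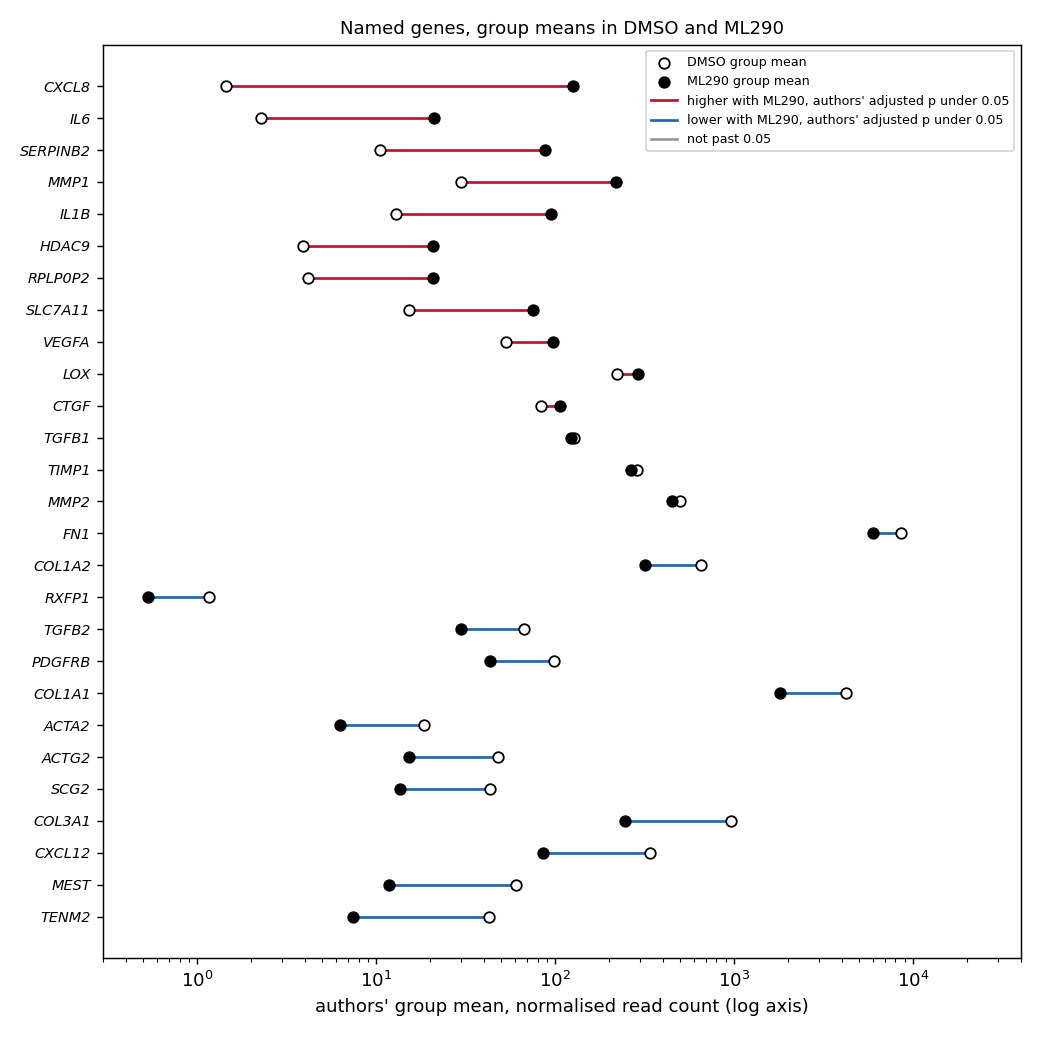
Group means of the named genes in DMSO (open points) and ML290 (filled points), as normalised read counts from the authors' deposited table on a log axis, with the line coloured by the authors' adjusted p. CXCL8 spans from 1.45 to 126.5 and RXFP1 lies at the low end, at 1.16 and 0.534.

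Collagen chains were lower as a group. Of 23 listed, 15 were lower and 2 higher in the authors' deposited table, with the same counts adjusted over the list alone, and the median log2 ratio was -0.65. None of 10000 random lists matched on level lay as low, which gives the smallest p they can give, 0.0002, or 0.00066 after adjustment over the 33 lists tested by this permutation. COL3A1 fell from 961.4 to 248.0 (adjusted p = 7.85e-10), COL6A3 was 2.65-fold lower (adjusted p = 1.70e-08) and COL5A2 1.87-fold lower (adjusted p = 6.07e-08) in the authors' deposited table. The main fibrillar chain COL1A1 had a mean of 4231 with DMSO and 1809.6 with ML290 in the authors' deposited table, 2.34-fold lower (adjusted p = 1.45e-06), and COL1A2 was 2.06-fold lower (adjusted p = 1.23e-06). COL27A1 and COL13A1 were the 2 higher chains, at 1.26-fold and 1.40-fold in the authors' deposited table. COL1A1 lies on chromosome 17 from 50183289 to 50201632 and COL3A1 on chromosome 2 from 188974320 to 189012746.

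Other matrix transcripts fell too. Of 30 matrix glycoproteins and proteoglycans, 22 were lower and 1 higher in the authors' deposited table (23 and 2 adjusted over the list alone), with a median log2 ratio of -0.63 and a random-list permutation p of 0.00066 after adjustment. IGFBP5 was 2.93-fold lower, THBS1, an activator of latent TGF-β, 2.17-fold lower and SPARC 2.07-fold lower in the authors' deposited table. Fibronectin, FN1, fell from 8539.5 to 5989.6, 1.43-fold lower (adjusted p = 0.00296) in the authors' deposited table. Among 21 collagen-modifying enzymes, 8 were lower and 3 higher in the authors' deposited table, the same counts adjusted over the list alone, with a median log2 ratio of -0.22 and an adjusted permutation p of 0.0227. Fisher's exact test of the share called did not pass for this list (adjusted p = 0.167). LOXL4, at a mean level under 10, was 5.11-fold lower and the collagen chaperone SERPINH1 1.53-fold lower in the authors' deposited table. The crosslinking enzyme LOX was 1.31-fold higher (adjusted p = 0.000419) in the authors' deposited table.

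Matrix-degrading enzymes did not move as a list. Of 17 matrix metalloproteinases, cathepsins and plasminogen activation genes, 8 were higher and 1 lower in the authors' deposited table (8 and 2 adjusted over the list alone), with a median log2 ratio of 0.10 (adjusted permutation p = 0.498). The list mean, 0.36, did pass the permutation test (adjusted p = 0.0242). The interstitial collagenase MMP1 rose from 30.03 to 220.2, 7.33-fold (adjusted p = 8.27e-08), and the urokinase receptor PLAUR was 1.63-fold higher, while the gelatinase MMP9 was 2.39-fold lower in the authors' deposited table. MMP2 had 451.9 with ML290 and 502.7 with DMSO (adjusted p = 0.221) in the authors' deposited table. Of 6 inhibitors of matrix degradation, 2 were higher and 2 lower in the authors' deposited table, the same counts adjusted over the list alone (median log2 ratio -0.08, adjusted permutation p = 0.884). TIMP3 was 1.97-fold lower and TIMP2 1.24-fold lower, and TIMP1 had 266.5 against 285.8 (adjusted p = 0.214) in the authors' deposited table.

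The contractile genes of myofibroblasts were lower with few exceptions. Of 19 listed, 17 were lower and 1 higher in the authors' deposited table, the same counts adjusted over the list alone, with a median log2 ratio of -0.66 (adjusted permutation p = 0.00066). ACTA2, the classical marker of activated stellate cells, fell from 18.7 to 6.27 (adjusted p = 8.90e-08), and the actin-binding proteins TAGLN and CALD1 were 2.65-fold and 1.86-fold lower in the authors' deposited table. Smoothelin, SMTN, was 1.23-fold higher and CNN1 had 9.65 against 9.78 (adjusted p = 0.919) in the authors' deposited table. The cytoplasmic actins, often used as reference genes, were lower as well, ACTB 1.78-fold and ACTG1 1.71-fold in the authors' deposited table. ACTA2 lies on chromosome 10 from 88935074 to 88991339.

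Transcripts known to be raised by TGF-β and SMAD3 split. Of 21, 7 were higher and 7 lower in the authors' deposited table, the same counts adjusted over the list alone. The lower ones included TAGLN, COL1A1, FN1 and TGFBI, all of which other lists here also hold, with TGFBI 2.04-fold lower in the authors' deposited table. The activin subunit INHBA was 2.37-fold higher, the cytokine IL11 1.59-fold, the inhibitory SMAD7 1.62-fold (adjusted p = 7.80e-05) and the growth factor CTGF 1.28-fold (adjusted p = 0.0103) in the authors' deposited table. INHBA, IL11, SMAD7 and CTGF are likewise in other lists here, IL11 among the inflammatory transcripts. The list median of -0.15 passed the random-list permutation (adjusted p = 0.0376), but the adjusted p was 0.064 without matching on level, 0.303 for the list mean and 0.0709 after a trend in transcript length and GC content was subtracted. Of 27 TGF-β ligands, receptors, SMADs and regulators, 7 were higher and 4 lower in the authors' deposited table, the same counts adjusted over the list alone (median log2 ratio 0.04, adjusted permutation p = 0.884). The repressor TGIF1 was 2.01-fold higher, the ligand TGFB2 2.23-fold lower (adjusted p = 3.83e-07), and TGFB1 had 123.7 against 128.4 (adjusted p = 0.706) in the authors' deposited table.

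Of 23 YAP and TAZ target genes, 12 were lower and 4 higher in the authors' deposited table, the same counts adjusted over the list alone, with a median log2 ratio of -0.22 (adjusted permutation p = 0.00704). This adjusted p was 0.0986 for the list mean and 0.0572 after the length and GC trend was subtracted. TGFB2 and AJUBA were lower, the latter 1.74-fold, and GADD45A, which is also a p53 target, was 2.16-fold higher in the authors' deposited table. CTGF, 1.28-fold higher in the authors' deposited table, is another of the 4 higher members. Among 15 genes of quiescent stellate cells, 3 were higher and 2 lower in the authors' deposited table, the same counts adjusted over the list alone (median log2 ratio 0.03, adjusted permutation p = 0.884). The transcription factor TCF21 went from 0.665 to 2.47 and the lipid droplet protein PLIN2 was 1.59-fold higher in the authors' deposited table.

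The receptor itself was near the floor. RXFP1 had a mean of 1.16 with DMSO and 0.534 with ML290 in the authors' deposited table, 2.18-fold lower (adjusted p = 0.0138), which corresponds to about 97.8 and 41.0 reads summed over the 4 libraries of each group. Of the relaxin peptides and receptors, the others listed were RXFP3, with 1.03 against 0.629 (adjusted p = 0.0591), and RXFP4, with 0.275 against 0.262 (adjusted p = 0.974), in the authors' deposited table. Adjusted over the list alone, RXFP3 also passed the threshold. RXFP1 lies on chromosome 4 from 158315311 to 158653372. Of 27 immediate targets of cAMP, PKA and CREB, 11 were higher and 5 lower in the authors' deposited table (12 and 5 adjusted over the list alone), with a median log2 ratio of 0.22 (adjusted permutation p = 0.0302). The hormone STC1 was 3.49-fold higher, the stress-responsive factor ATF3 3.21-fold, the orphan receptor NR4A1 2.39-fold and FOSB 3.30-fold in the authors' deposited table. These named members are all from the higher side, while over the list 15 ratios lay above 1 and 12 below. Of 13 genes of nitric oxide, cyclic GMP and endothelin signalling, 4 were lower and 0 higher in the authors' deposited table, the same counts adjusted over the list alone (median log2 ratio -0.09, adjusted permutation p = 0.71). The endothelin-converting enzyme ECE1 was 1.23-fold lower and the natriuretic peptide receptor NPR3 1.53-fold lower in the authors' deposited table, and NOS2 and EDNRB were not listed.

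Inflammatory transcripts had the largest list median of the 33 tested lists. All 28 listed NF-κB cytokines, chemokines and adhesion molecules passed the threshold of the authors' deposited table, 24 higher and 4 lower, the same counts adjusted over the list alone, with a median log2 ratio of 1.55 (adjusted permutation p = 0.00066). Mitochondrial superoxide dismutase, SOD2, was 4.89-fold higher, the adhesion molecule ICAM1 2.89-fold, the NF-κB inhibitor TNFAIP3 4.14-fold and the chemokine CXCL2 19.4-fold, from 0.452 to 8.74, in the authors' deposited table. The 4 lower members were CXCL12, CCL7, CCL2 and VCAM1, the last 1.79-fold lower at a mean under 2 in the authors' deposited table. Of 32 interferon-stimulated genes, 12 were higher and 10 lower in the authors' deposited table (12 and 12 adjusted over the list alone). IFIT2 was 2.21-fold and OASL 3.61-fold higher, and OAS3 was 1.44-fold lower in the authors' deposited table. The list's median log2 ratio was -0.15 (adjusted permutation p = 0.0173) and its mean was 0.09 (adjusted p = 0.627), which differ in sign.

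**Figure D2:**
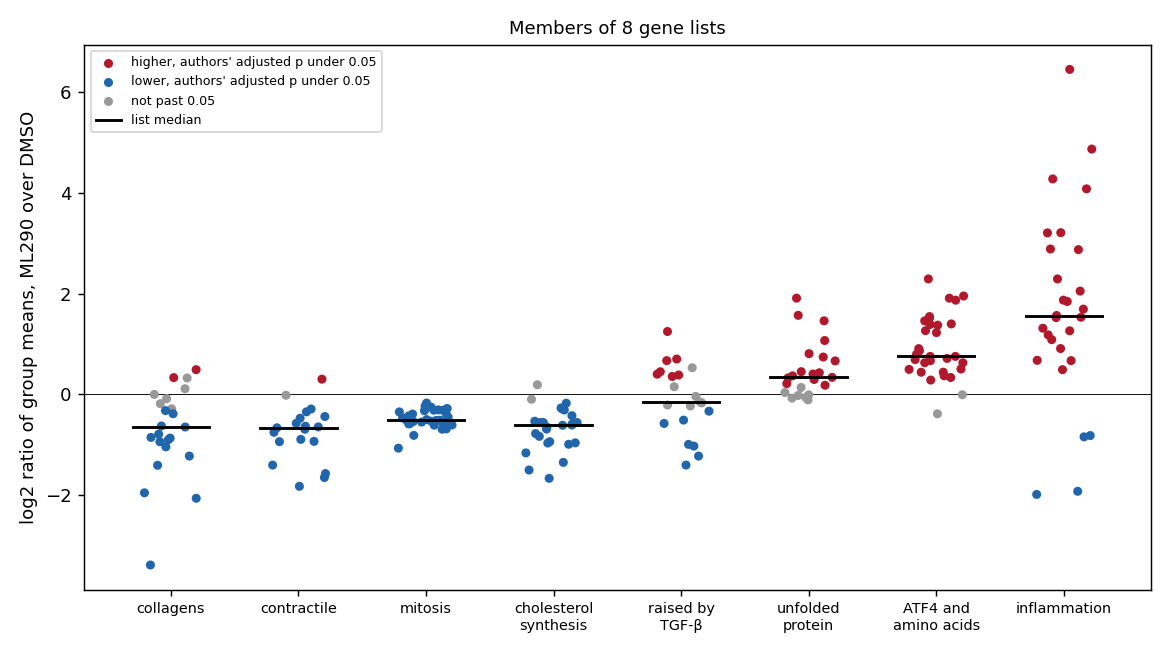
Log2 ratio of ML290 over DMSO group means for each member of 8 gene lists, from the authors' deposited table, with the list median as a bar and colour by the authors' adjusted p. Inflammatory and ATF4 list medians lie at 1.55 and 0.75, mitosis and cholesterol medians at -0.51 and -0.61, and the transcripts raised by TGF-β lie on both sides of 0.

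Genes of amino acid supply and ATF4, the transcription factor of the integrated stress response, were higher. Of 31, 29 were higher and 0 lower in the authors' deposited table (29 and 1 adjusted over the list alone), with a median log2 ratio of 0.75 (adjusted permutation p = 0.00066). SLC3A2, the partner chain of SLC7A11, rose from 150.3 to 581.5 (adjusted p = 3.71e-10), the stress factor DDIT3 was 3.75-fold higher, the pseudokinase TRIB3 2.86-fold and ATF4 1.74-fold in the authors' deposited table. Of 23 genes of the unfolded protein response, 16 were higher and 0 lower in the authors' deposited table, the same counts adjusted over the list alone (median log2 ratio 0.34, adjusted permutation p = 0.00066). HERPUD1 was 2.75-fold higher, XBP1 2.10-fold and the chaperone HSPA5 1.67-fold in the authors' deposited table, and DDIT3 belongs to both lists. Among 24 autophagy and lysosome genes, 20 were higher and 1 lower in the authors' deposited table, the same counts adjusted over the list alone (median log2 ratio 0.41, adjusted permutation p = 0.00066). The autophagy receptor SQSTM1 rose from 268.2 to 714.3, WIPI1 was 2.44-fold and the lysosomal cholesterol transporter NPC1 1.79-fold higher, and the lower member was TFEB, 1.72-fold, in the authors' deposited table. Of 23 p53 targets, 12 were higher and 2 lower in the authors' deposited table (13 and 2 adjusted over the list alone), with a median log2 ratio of 0.35 (adjusted permutation p = 0.0018). The cell cycle inhibitor CDKN1A was 2.06-fold higher, the death receptor TNFRSF10B 1.64-fold and SESN2, also an ATF4 target, 2.40-fold in the authors' deposited table.

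Cholesterol synthesis was lower almost throughout. Of 26 listed genes, 24 were lower and 0 higher in the authors' deposited table, the same counts adjusted over the list alone, with a median log2 ratio of -0.61 (adjusted permutation p = 0.00066). HMGCS1 fell from 201.1 to 71.0, ACAT2 was 2.55-fold lower and FDFT1 1.78-fold lower in the authors' deposited table. Of 28 fatty acid genes, 13 were lower and 6 higher in the authors' deposited table (14 and 7 adjusted over the list alone), with a median log2 ratio of -0.21 (adjusted permutation p = 0.00254). The desaturases SCD and FADS2 were 1.97-fold and 1.88-fold lower, and PPARA, a receptor that drives fatty acid oxidation, was 2.00-fold higher in the authors' deposited table.

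Mitotic genes fell without exception in the list, with 34 of 34 lower in the authors' deposited table, the same counts adjusted over the list alone, and a median log2 ratio of -0.51 (adjusted permutation p = 0.00066). The mitotic kinesin KIF20A was 2.10-fold lower and the proliferation marker MKI67 fell from 609.7 to 346.6 in the authors' deposited table. Of 33 DNA replication genes, 21 were lower and 2 higher in the authors' deposited table, the same counts adjusted over the list alone (median log2 ratio -0.26, adjusted permutation p = 0.00066). UHRF1 and MCM10 were each 1.39-fold lower in the authors' deposited table. Of 19 growth factors and their receptors, 8 were higher and 8 lower in the authors' deposited table (10 and 8 adjusted over the list alone). PDGFRB, the receptor of the main stellate cell mitogen, was 2.26-fold lower and PDGFRA 2.09-fold lower, while VEGFA was 1.84-fold and FGF5 2.08-fold higher in the authors' deposited table. The list median of 0.25 (adjusted permutation p = 0.0175) was not past the threshold as a mean, 0.09 (adjusted p = 0.704), or after the length and GC trend was subtracted (adjusted p = 0.0914).

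**Figure D3:**
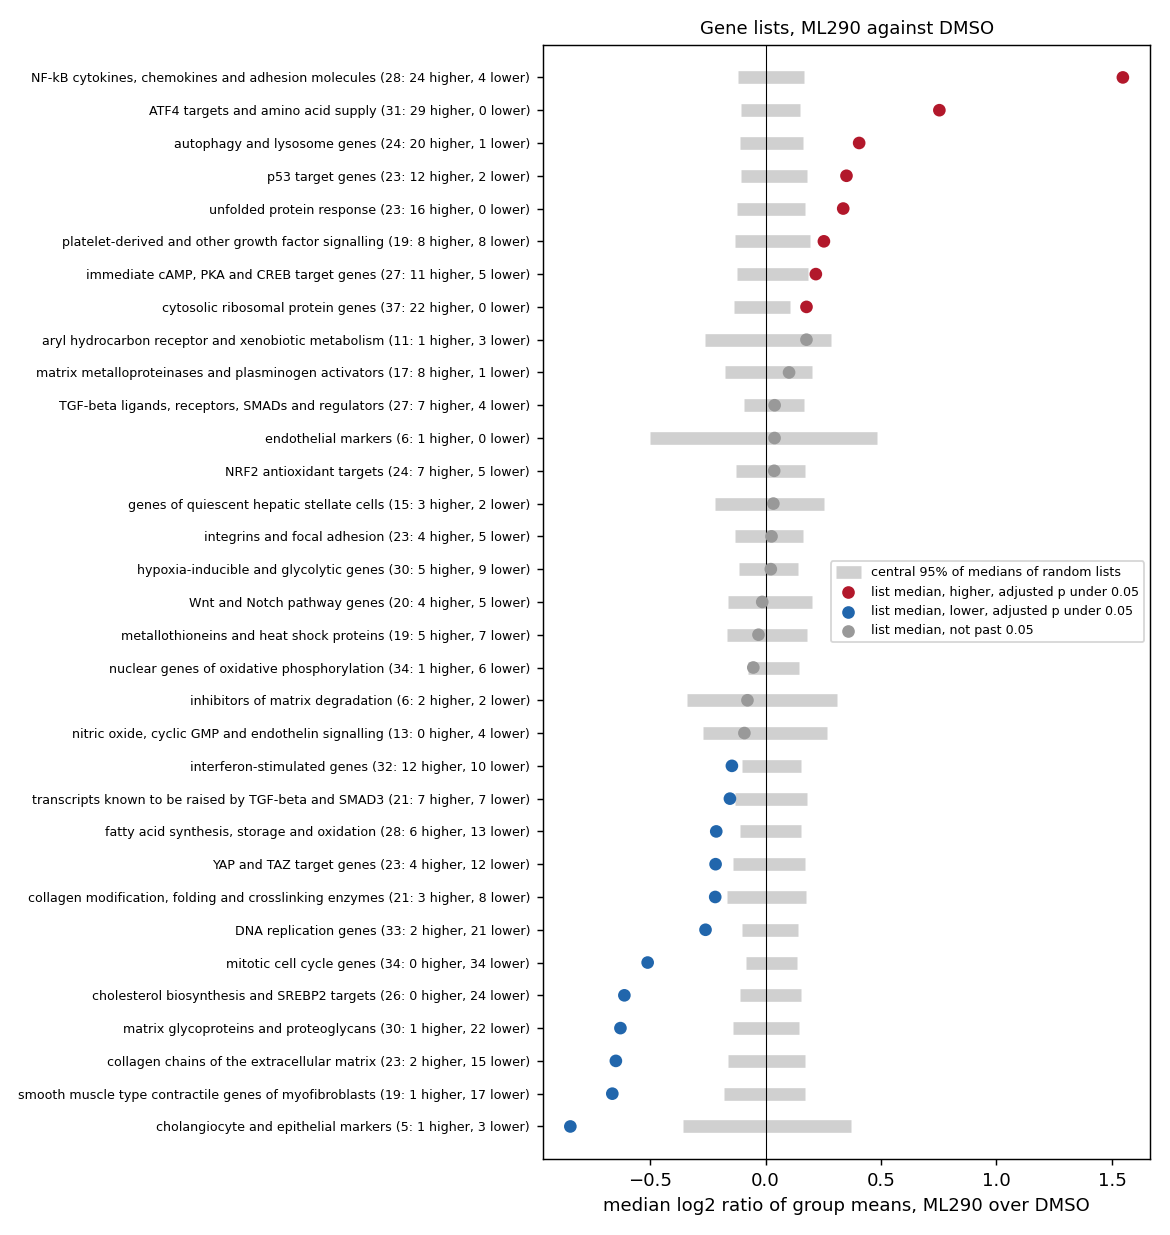
Median log2 ratio of ML290 over DMSO for the 33 tested lists (points), computed from the authors' deposited table, with the central 95% of medians of 10000 random lists matched on level as grey bars and the listed, higher and lower members in the row names. Inflammation lies highest at 1.55 and the cholangiocyte and epithelial markers lowest at -0.85. The collagen, matrix glycoprotein, contractile, mitosis and cholesterol lists lie between -0.51 and -0.66.

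Several lists had members on both sides and medians inside the range of random lists. Of 24 NRF2 targets, 7 were higher and 5 lower in the authors' deposited table (7 and 6 adjusted over the list alone; median log2 ratio 0.04, adjusted permutation p = 0.884), with the ferritin chains FTL and FTH1 1.92-fold and 1.53-fold higher. Of 30 hypoxia and glycolysis genes, 5 were higher and 9 lower in the authors' deposited table (7 and 10 adjusted over the list alone; median 0.02, adjusted permutation p = 0.884), with ENO2 1.74-fold higher and LDHA 1.61-fold lower. Of 19 metallothioneins and heat shock proteins, 5 were higher and 7 lower in the authors' deposited table, the same counts adjusted over the list alone (median -0.03, adjusted permutation p = 0.884), with MT2A 1.41-fold higher and HSPB1 1.65-fold lower. Of 11 xenobiotic genes, 1 was higher and 3 lower in the authors' deposited table (2 and 4 adjusted over the list alone, median 0.18, adjusted permutation p = 0.364), with CYP1B1 2.30-fold and GSTA4 2.53-fold lower. The mean log2 ratio of the xenobiotic list was -0.13 (adjusted permutation p = 0.607), opposite in sign to its median. Of 34 nuclear genes of oxidative phosphorylation, 1 was higher and 6 lower in the authors' deposited table (1 and 3 adjusted over the list alone; median -0.05, adjusted permutation p = 0.196), with COX4I1 1.18-fold higher and NDUFB8 1.15-fold lower. Of 23 integrin and focal adhesion genes, 4 were higher and 5 lower in the authors' deposited table (5 and 6 adjusted over the list alone; median 0.03, adjusted permutation p = 0.884), with ITGA2 2.11-fold higher and ITGA4 1.83-fold lower. Of 20 Wnt and Notch genes, 4 were higher and 5 lower in the authors' deposited table, the same counts adjusted over the list alone (median -0.01, adjusted permutation p = 0.884), with HEY1 6.98-fold higher from a mean of 0.178 and NOTCH3 1.80-fold lower. Ribosomal protein genes rose slightly, 22 of 37 higher and 0 lower in the authors' deposited table (23 and 0 adjusted over the list alone), with a median log2 ratio of 0.18 (adjusted permutation p = 0.00704) and RPL10 1.28-fold higher.

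Markers of other liver cells were mostly not listed. Of 22 hepatocyte markers 4 were listed, with CPS1 1.44-fold lower and none higher in the authors' deposited table, the same adjusted over the list alone. Of 12 cholangiocyte and epithelial markers 5 were listed, 3 lower and 1 higher in the authors' deposited table, the same counts adjusted over the list alone (median log2 ratio -0.85, adjusted permutation p = 0.0022; list mean -0.47, adjusted p = 0.0485). The lower ones were the keratins KRT8, KRT18 and KRT7, 2.09-fold, 2.09-fold and 1.80-fold in the authors' deposited table, and they fell alongside the contractile and matrix genes. Of 6 listed endothelial markers, TIE1 was 1.38-fold higher and none lower in the authors' deposited table, the same adjusted over the list alone (median log2 ratio 0.04, adjusted permutation p = 0.884). Of 4 listed leukocyte markers, the lysosomal protein CD68 was 2.04-fold higher and CD14 1.501-fold lower in the authors' deposited table, the same counts adjusted over the list alone, and CD68 rose with the lysosome genes. Transcripts of the mitochondrial genome, a sign of RNA quality, were not listed. Ribosomal RNA made up 8.21% of the ML290 sum and 8.16% of the DMSO sum in the authors' deposited table.

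In all, 20 of 33 tested lists passed the random-list permutation, 8 higher and 12 lower with ML290 by the sign of the median. Among them, transcripts raised by TGF-β, YAP and TAZ targets, interferon-stimulated genes and growth factors did not pass with the list mean. Genes of a list are not independent of each other, so the random-list p-values are too small. The p-values of the authors' deposited table rest on these samples alone. The series text calls them biological replicates without saying whether they came from separate cultures.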

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

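The unadjusted threshold, the centring, the removal of chromosome 6 rows and the length and GC trend were chosen after the data were seen. Of 5226 genes past the threshold, 2901 higher and 2325 lower, an adjusted p under 0.01 left 3413 (1922 and 1491), a fold of at least 1.5 left 1604 (894 and 710) and a fold of at least 2 left 598 (319 and 279). Fewer genes meet a stricter rule by construction. Of the 598 genes, 189 had a mean level of at least 10, 125 higher and 64 lower, so the balance of directions depended on level. An unadjusted p under 0.05 gave 6536 genes, 3580 higher and 2956 lower. Adjustment over the listed rows alone gave 5226, levels above the lower quartile 4815, and removal of chromosome 6 rows and doubled symbols 5186. Centring on the median of all genes moved every log2 ratio alike by 0.02 with the p-values kept, so its equal counts say nothing about stability.

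Of 33 tested lists, 20 passed in the main test, 19 without matching on level, 17 with the list mean and 17 after the length and GC trend was subtracted. The list of transcripts raised by TGF-β lost its permutation call in each of these, with medians of -0.15 unmatched (adjusted permutation p = 0.064) and -0.16 without the trend (0.0709) and a mean of -0.10 (0.303). YAP targets lost it with the mean, -0.15 (0.0986), and without the trend, -0.17 (0.0572), and growth factors with the mean, 0.087 (0.704), and without the trend, 0.17 (0.0914). Interferon-stimulated genes turned from a median of -0.15 to a mean of 0.0904 (0.627). Matrix degradation passed only with the mean, 0.36 (0.0242). The cause was not tested.

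No paired analysis was possible because the table holds no values per sample. For the same reason leaving out each sample in turn, other splits of the samples, other count tests and normalizations, and other set tests were not run, and no sample was checked as an outlier. Low genes such as RXFP1 rest on few reads.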

Other observations

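The grouping of genes by symbol, the scaling test, the test of the transcripts raised by TGF-β and both tests of shared reads were chosen after results were seen. Symbols were grouped first by a short start of their letters, which cut some family names short, and then, once those results were known, by all letters before the first digit. The first grouping passed 19 of 176 families by the random-list permutation and the second 11 of 206, and the families below are a selection from both.

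Tubulins, the subunits of microtubules, were lower in the first grouping, 11 of 15 lower and 1 higher with a median log2 ratio of -0.56 (adjusted permutation p = 0.00503). The group holds the pseudogene TUBA3FP. TUBA1A fell from 319.9 to 122.1 and TUBB3 was 2.18-fold lower, while TUBE1 was 1.601-fold higher in the authors' deposited table. The second grouping splits tubulins into groups too small for its test. Dual-specificity phosphatases, many of which dephosphorylate MAP kinases, were higher, 12 of 18 in the second grouping and none lower (median log2 ratio 0.40, adjusted permutation p = 0.00589), with DUSP8 2.77-fold and DUSP16 1.73-fold higher in the authors' deposited table. Genes whose symbols start with SEC, many of them parts of the transport of proteins into and out of the endoplasmic reticulum, had 15 of 26 higher and 2 lower (median log2 ratio 0.33, adjusted permutation p = 0.0103), with SEC24A 1.90-fold and SEC61A1 1.52-fold higher in the authors' deposited table. The solute carriers had 89 of 213 higher and 19 lower (median log2 ratio 0.16, adjusted permutation p = 0.00589) in the second grouping.

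Glutathione S-transferases had 6 of 10 lower and 1 higher in the first grouping (median log2 ratio -0.48, adjusted permutation p = 0.0147), with GSTM2 1.55-fold lower and GSTO1 1.68-fold higher in the authors' deposited table. Small nucleolar RNA host genes had 9 of 18 higher and 1 lower in the first grouping (adjusted permutation p = 0.0391) and an adjusted permutation p of 0.0775 in the second, with SNHG5 1.85-fold higher in the authors' deposited table. Beta protocadherins had 9 of 14 lower and none higher in both groupings (median log2 ratio -0.47), but they are close copies whose reads are uncertain.

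The first pattern weighed is that amino acid, unfolded protein and inflammatory lists were higher while the cholesterol list was lower. One scaling factor between the groups would move all of them the same way, and the pattern itself, with the cholesterol median at -0.61 below the median of all genes and the other 3 above it, is what such a factor alone does not give. A trend in transcript length or GC content was subtracted, and each of the 4 medians kept at least 90.4% of its value. These values argue against both as the whole cause, the first by the pattern's own values and not by a separate test. The pattern may be an effect of ML290, but whether it runs through RXFP1, which was near the floor, or apart from the receptor stays open, since no group lacked the receptor.

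The second pattern is that the collagen, matrix glycoprotein and contractile lists were lower. After the length and GC trend was subtracted, each of the 3 medians kept at least 95.6% of its value, which argues against that trend as the whole cause. A hypothesis is that ML290 lowered all transcripts that TGF-β raises, but 7 called members of that list were higher, among them SMAD7 and INHBA. These values argue against a uniform fall of the list's members, by a split known beforehand and not by a separate test. The list was drawn up as early targets, and the cells were taken at 72 h. A fall of a part of these transcripts stays open, and no group without TGF-β1 shows whether or how far each had been raised in these cells.

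The third pattern is that 12 rows, of 11 genes, with a level of at least 10 and a log2 ratio beyond 0.7 either way did not pass the threshold. Of these rows 6 lie between 28 and 34 Mb of chromosome 6, against 85 of 8860 rows at that level (Fisher's exact two-sided p = 5.75e-10), or 5 of 11 genes against 84 of 8859 with each symbol counted once (p = 3.00e-08 by the same exact test), and 4 of 10 without BRD2 (p = 1.44e-06 by the same exact test). BRD2, the only symbol listed in 2 rows, was 3.39-fold higher in one row and 2.89-fold lower in the other in the authors' deposited table, and the summed rows gave a ratio of 1.11. GRCh38 also holds this region as alternative sequences, and reads split between copies are a candidate source of such rows, but the region and BRD2 were both picked from the rows they were tested on, so these values do not decide it. No biological explanation was tested.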
